A study of Mus musculus with 6 samples.

How the data were processed

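RNA of FACS-sorted YFP-positive ureteric bud cells from E15.5 mouse kidneys was profiled on Affymetrix whole-transcript arrays, per the labels' protocols. 3 arrays held control cells and 3 held Dicer mutant cells, with the genotype written as Dicerc/-; Hoxb7Cre; Rosa26YFP for the mutant and as wild type for the control. Whether the control cells, which were sorted on YFP too, carried Hoxb7Cre and Rosa26YFP is not given, so an effect of Cre is not separated from that of the Dicer genotype. The values deposited by the authors are RMA expression values on the log2 scale, 1 per probe set and array. RMA and the affy package are named in the submitters' processing notes, and their versions, the genome build and any filter are not given in the sources used here. RMA corrects the background, forces the arrays to a common distribution and summarises probes on a log scale, so a shift that affected most transcripts alike would be removed and changes of dim genes are compressed. The log2 scale was checked on the values, which ran from 2.26 to 14.11. The replicates are called biological in the labels, but whether an array held 1 embryo or a pool is not given, so p-values measure the spread between these samples. No 2 arrays shared more than 22 identical values, so each was counted as a sample. No batch, slide or date was given in the sources used here.

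Of 23309 probe sets, 20728 had 1 gene symbol in the platform annotation, 1174 had several, and 1407 were not listed there and are unnamed here. Symbols were compared with a RefSeq gene table (assembly GRCm38.p6) through the gene ID, which 20685 probe sets matched with 0 symbols changed. Only probe sets with 1 symbol were named, and for genes with several the one with the highest mean over all 6 arrays was kept, leaving 19296 genes. No coordinates are printed because the files name no build. No filter on intensity was applied, and the table holds no detection call. "Dim" is therefore relative to the median of all probe sets, 7.51, and says nothing about the scanner's background. The alternative without dim genes kept genes whose mean in at least 1 group lay above that median. Counts by brightness used the mean over all 6 arrays, unless a group is named.

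Both groups entered 1 linear model per gene with genotype as its only term (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 3.93 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05, and all tests were two-sided. For Dicer1 an exact permutation test was added. The design, the gene lists, the naming rule and the alternatives were fixed before the data were examined. The naming rule took the 13 genes with the largest rise and the 13 with the largest fall among those past the threshold whose arrays did not overlap between groups. It added Dicer1 and, of each list, up to 4 members past the threshold by smallest p, or the 2 with the smallest p where none passed. Other members were named after their values were seen: Drosha, Dgcr8, Acvr1c, Ccnd2, Hmga2, Zeb1, Zeb2, Ret, Gfra1, Mycn, Krt19, Cdh1, Epcam, Tfcp2l1, Krt5, Krt14, Ift88, Fas, Trp53inp1, Mdm2, Bbc3, Cited1, Eya1 and Gdnf.

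The 30 lists covered miRNA machinery and target sets, ureteric and collecting duct cell types, signalling and stress responses, the cell cycle, and markers of the other cell types a kidney sort could hold. They were drawn from general knowledge, which for Lin28b, Lgr5 and Trp63 includes the study's publication. List genes without a probe set of their own were not analysed here. Each list was tested with camera (preset correlation 0.01), adjusted over the 30 lists, and again with an estimated correlation and with fry. Members past the threshold were counted over all genes and adjusted over the list alone. Intervals of list medians came from 10000 bootstrap draws over genes.

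The fit was tested on simulated arrays of the same 19296 genes and 3 against 3 samples. It recovered 68% of 50 genes changed by 0.5 on the log2 scale, 96% at 1 and 100% at 2 and at 3, and called 8 unchanged genes. Camera called the list of 20 moved genes and 0 of 100 unmoved lists. The simulated genes varied independently of one another, whereas the correlation estimated within the real lists reached 0.63 (principal cell). The simulation therefore does not show how often camera with the preset 0.01 calls correlated lists by mistake. The alternatives were the replicate number as a block, each array left out, quantile normalization, median centring, dim genes left out, the mean of a gene's probe sets, a variance trend with robust eBayes, array weights, every probe set, other thresholds, other set tests, and lists without genes shared with another list. Counts by brightness and 7 further lists were added after the values were seen. Figures were drawn with matplotlib 3.10.9.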

Results

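Gene expression was measured on Affymetrix whole-transcript arrays in ureteric bud cells of mouse kidneys at E15.5, a stage at which the ureteric bud branches and nephrons form. The ureteric bud is the branching epithelium that forms the collecting ducts and signals to the surrounding mesenchyme, from which the nephrons arise. Of the 6 arrays, 3 held control cells and 3 held cells of Dicer mutant kidneys. In the mutant (Dicerc/-), Hoxb7Cre, a Cre transgene active in the ureteric bud, acts on a conditional Dicer allele. A Rosa26YFP reporter marks the cells in which Cre was active. The other Dicer allele is null and does not depend on Cre, so an effect of it in cells outside the bud is not separated here. Cells of both groups had been dissociated with trypsin and sorted on YFP. The control genotype is given as wild type, so whether it carried Hoxb7Cre and Rosa26YFP is not stated, and an effect of Cre is not separated here from that of the Dicer genotype. Dicer cuts precursor hairpins into mature miRNAs, and the comparison addressed which transcripts differed between mutant and control ureteric bud cells. The strain background was mixed in both groups. The arrays were alike in scale, with medians of 7.47 to 7.54 on the log2 scale over 23309 probe sets. Pearson's r across probe sets, which are not independent replicates, was 0.996 to 0.998 within groups and 0.988 to 0.992 between them. The first principal component held 65.8% of the variance and separated the groups. The median SD of a gene was 0.0884 log2 units between control arrays and 0.0707 between mutant arrays, and the number of arrays limits the precision of every value.

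Dicer1, the targeted gene (probe set 10402444), was lower in the mutant cells on all 3 arrays. Its level was 10.31 ± 0.06 (SD, n = 3) in control cells and 9.72 ± 0.08 (SD, n = 3) in mutant cells, on the log2 scale. The log2 fold change was -0.59 with a standard error of 0.06, so the mutant signal was 66.3% of the control signal (limma, adjusted p = 0.0005). A two-sided exact permutation test of the 3 against 3 values gave p = 0.1, the smallest this design allows. Probes outside the deleted exons could not be told from those inside, and what the null allele adds to the signal is not given. The remaining signal therefore does not measure how many cells had lost the enzyme.

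The mutant cells differed from control cells across a large part of the transcriptome, mostly by less than 2-fold. In limma's test, 4975 of 19296 genes (25.8%) passed an adjusted p of 0.05, of which 2285 were higher and 2690 lower in the mutant. The median log2 fold change of the higher genes was 0.38 and that of the lower genes -0.35. The share that passed was 39.6% among genes above the median brightness and 11.9% among those below it. Changes of at least 2-fold were found for 208 genes, and here more genes were higher (144) than lower (64). Which direction held more genes overall depended on the scaling: centring each array on its median gave 2696 higher and 2241 lower genes. Without mutant replicate 1 the count of lower genes was 1764.

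The largest rise was that of Hapln1, a link protein of the hyaluronan matrix, from 6.05 ± 0.40 to 10.07 ± 0.09 (SD, n = 3 each; 16.1-fold, adjusted p = 1.69e-05). Lhx8, a LIM homeodomain transcription factor, rose 13.2-fold, and Tinag, a basement membrane protein, rose 12.1-fold. Six2, the transcription factor that maintains nephron progenitors in the cap mesenchyme, rose from 7.05 ± 0.21 to 10.34 ± 0.06 (SD, n = 3 each; 9.78-fold, adjusted p = 3.29e-06). Prtg, a membrane protein of the early embryo and a let-7 target, rose 7.03-fold from 7.74 ± 0.02 to 10.56 ± 0.09 (SD, n = 3 each). Among the other genes with large rises, 4 encode secreted proteins or matrix receptors: the protease inhibitor Spink12 (6.24-fold), Cthrc1 (5.77-fold), the integrin subunit Itgb8 (5.55-fold) and the protease Htra3 (5.43-fold). The NADPH oxidase Nox4 (5.37-fold), the receptor phosphatase Ptprz1 (5.17-fold), the calcium sensor Doc2b (4.89-fold) and the TNF receptor family member Eda2r (4.52-fold) completed the 13 genes with the largest rises. The adjusted p of these 13 genes was at most 5.37e-05. In control cells all of them except Prtg, Cthrc1, Nox4 and Ptprz1 lay below the median of all probe sets, 7.51.

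The largest fall was that of Lcn2, a secreted siderophore-binding lipocalin, from 9.24 ± 0.50 to 6.67 ± 0.22 (SD, n = 3 each; 5.94-fold lower, adjusted p = 0.000214). The methyltransferase Inmt was 5.39-fold lower. Sprr1a and Sprr2f, cornified envelope proteins of stratified epithelia, were 4.53-fold and 2.86-fold lower, and the uroplakin Upk1b was 3.19-fold lower. The mitochondrial carbonic anhydrase Car5b fell by 2.00 on the log2 scale, and the potassium channel Kcnh5 (3.43-fold) and the secreted protein Lgi3 (3.36-fold) were also lower. Ror1, a receptor for Wnt5a, fell from 10.51 ± 0.05 to 8.78 ± 0.01 (SD, n = 3 each; 3.30-fold lower, adjusted p = 3.29e-06). Adh1, an alcohol dehydrogenase, was 2.94-fold lower, the GABA receptor subunit Gabrg1 2.92-fold, the protease cathepsin E (Ctse) 2.77-fold and the growth factor Nrg3 2.70-fold. The adjusted p of these 13 genes was at most 0.00455. Gabrg1 and Sprr2f lay below the median of all probe sets in both groups.

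**Figure D1:**
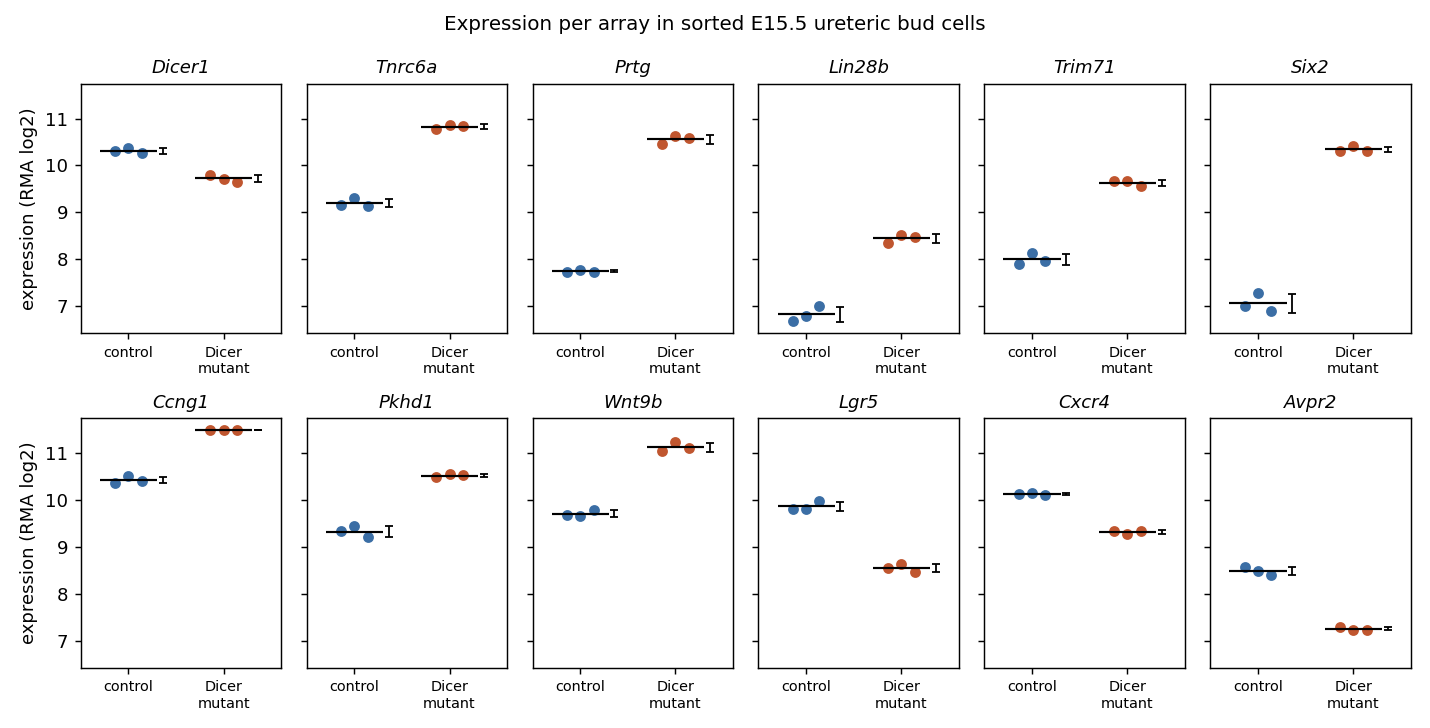
Expression of 12 named genes on each of the 6 arrays, as RMA values on the log2 scale. Points are arrays, horizontal lines are group means and bars are the SD (n = 3). Six2 lay near 7.05 in control cells and near 10.34 in mutant cells, and in each panel the 3 mutant arrays lay on one side of all 3 control arrays.

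Gene groups were tested with camera against all other genes, and 14 of 30 lists passed an adjusted p of 0.05, 7 higher and 7 lower. With a correlation between genes estimated from these 6 arrays in place of the preset 0.01, 0 of the 30 lists passed in camera. At an unadjusted p under 0.05 that test still had the miRNA machinery, let-7, miR-200, miR-17 cluster, p53 and urothelial lists. The directional self-contained test fry called 17 lists. Counts of members past the threshold stand against the share of all genes that passed in either direction. This was 39.6% above the median brightness and 11.9% below it. For lists with mostly dim members, such as interferon response (2 of 13 above the median), 39.6% is therefore too high a base. The cystic disease and cilia list (15 of 16 genes above the median) and the mitosis list (20 of 20) did not exceed the 39.6%. The miRNA machinery and miR-17 cluster lists (12 of 13 each) lay near the 39.6%.

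Of 13 measured genes of the miRNA machinery, 5 rose in the mutant cells, 1 (Dicer1) fell and 7 did not pass (6 higher and 1 lower adjusted over the list alone). The list was higher in camera (adjusted p = 0.000133) and was not called with an estimated correlation (adjusted p = 0.226). Tnrc6a, a GW182 scaffold of the silencing complex, rose 3.09-fold from 9.20 ± 0.09 to 10.83 ± 0.05 (SD, n = 3 each). The Argonaute genes Ago3 and Ago2 rose by log2 fold changes of 0.85 and 0.68, and Tnrc6b by 0.64. Drosha and Dgcr8, which act before Dicer, had log2 fold changes of 0.02 and 0.16 and did not pass.

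Targets of let-7, a miRNA family that represses embryonic growth genes, showed the lowest p of the 30 lists. Of 21 measured targets, 14 rose, 2 fell and 5 did not pass (15 higher and 2 lower adjusted over the list alone), with a median log2 fold change of 0.43. Besides Prtg, the ubiquitin ligase Trim71 rose 3.10-fold, Lin28b, the RNA-binding protein that blocks let-7 maturation, rose 3.07-fold, and the transcription factor Arid3a rose 2.25-fold. Acvr1c and Ccnd2 fell, with log2 fold changes of -0.34 and -0.27. Hmga2, a well-known let-7 target, had a log2 fold change of 0.13 and did not pass. The list was higher in camera (adjusted p = 7.19e-10; adjusted p = 0.0999 with an estimated correlation). Lin28b was put on this list with knowledge of the study's publication, so the list is not fully independent of these samples.

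Targets of the miR-200 family, which helps to maintain epithelial identity, rose in 7 of 13 measured genes, fell in 1 and did not pass in 5 (8 higher and 1 lower adjusted over the list alone). The risen members included Sec23a, of the secretory vesicle coat (log2 fold change 0.98), the polycystin Pkd1 (0.80), the actin regulator Cfl2 (0.66) and fibronectin, Fn1 (0.53). The mesenchymal repressors Zeb1 and Zeb2, its best-known targets, had log2 fold changes of -0.07 and 0.03 and did not pass. Camera placed the list higher (adjusted p = 0.00119; adjusted p = 0.226 with an estimated correlation). Targets of the miR-17 cluster rose in 5 of 13 measured genes, fell in 1 and did not pass in 7 (6 higher and 1 lower adjusted over the list alone). The pro-apoptotic gene Bcl2l11 rose 2.50-fold, the matricellular gene Ccn2 2.16-fold and the receptor Tgfbr2 1.33-fold, whereas E2f2 had a log2 fold change of -0.44. That list was higher in camera (adjusted p = 0.0118), but not with an estimated correlation (adjusted p = 0.226) nor when dim genes were left out (adjusted p = 0.111).

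Genes of the ureteric tip, the growing end of the bud, were lower in the mutant cells. Of 18 measured tip genes, 13 fell, 1 rose and 4 did not pass (14 lower and 2 higher adjusted over the list alone), and the median log2 fold change was -0.39. The chemokine receptor Cxcr4 fell from 10.13 ± 0.02 to 9.33 ± 0.04 (SD, n = 3 each), a log2 fold change of -0.80. Sox8 (-0.79), Myb (-0.77) and Wnt11 (-0.60), a signal of the tip to the mesenchyme, fell likewise. Ret, the GDNF receptor of the tip, and its co-receptor Gfra1 both had log2 fold changes of -0.35. Mycn, which is also on the let-7 list, was the member that rose, by 0.46. Camera placed the list lower (adjusted p = 0.000105; adjusted p = 0.227 with an estimated correlation). In the same arrays 9 of 13 genes of the dissociation and immediate early list were lower, and 79 markers of 9 other lineages had a median log2 fold change of -0.09, with 7 higher and 9 lower. The median over all genes was -0.05, and -0.07 for genes below the median brightness. Only 17 of the 79 lay above the median brightness. Of the 79, the 14 early nephron and distal tubule genes had a median of 0.11.

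Genes of the ureteric epithelium at large fell in 9 of 18 measured members, rose in 1 and did not pass in 8, with the same counts adjusted over the list alone. Wnt9b, the bud's signal that induces nephrons, was the exception and rose 2.67-fold from 9.71 ± 0.07 to 11.13 ± 0.09 (SD, n = 3 each). The transcription factors Ehf, Hoxb7 and Pax8 had log2 fold changes of -0.73, -0.40 and -0.37. Krt19 fell by 1.19 on the log2 scale, while Cdh1 and Epcam (0.03 and -0.10) did not pass. The list was lower in camera (adjusted p = 0.0302; adjusted p = 0.227 with an estimated correlation), and without control replicate 3 it was not called (adjusted p = 0.115).

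Principal cell genes, which mark the water- and sodium-transporting cells of the collecting duct, fell in 8 of 12 measured members, rose in 1 and did not pass in 3, with the same counts adjusted over the list alone. The vasopressin receptor Avpr2 fell from 8.49 ± 0.09 to 7.25 ± 0.04 (SD, n = 3 each; 2.35-fold lower). The transcription factor Elf5 (log2 fold change -0.88), the water channel Aqp3 (-0.77) and the sodium channel subunit Scnn1b (-0.49) were also lower, and Tfcp2l1 was higher (0.26). The list was lower in camera (adjusted p = 0.0040; adjusted p = 0.618 with an estimated correlation). Intercalated cell genes, which mark the acid-base transporting cells, rose in 1 of 11 members, Kit (log2 fold change 0.38), and did not pass in 10 (the same counts adjusted over the list alone). Camera did not call that list (adjusted p = 0.737), its direction turned with dim genes left out (adjusted p = 0.387), and only 2 of the 11 genes lay above the median brightness.

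Urothelial and basal cell genes fell in 7 of 13 measured members and did not pass in 6, with the same counts adjusted over the list alone. Of the 7, 5 were uroplakins, the plaque proteins of the urothelium, with log2 fold changes of -1.67 for Upk1b, -1.31 for Upk3a and -1.16 for Upk3b. Trp63, the transcription factor of basal cells, fell by 0.44 on the log2 scale, whereas the basal keratins Krt5 and Krt14 (-0.14 and -0.18) did not pass. The list was lower in camera (adjusted p = 0.0040; adjusted p = 0.226 with an estimated correlation). Trp63 was chosen with knowledge of the study's publication, as was Lgr5 in the Wnt list, so neither list is fully independent of these samples.

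Targets of canonical Wnt signalling fell in 5 of 12 measured members, rose in 1 and did not pass in 6 (the same counts adjusted over the list alone). Lgr5, the R-spondin receptor, fell from 9.87 ± 0.10 to 8.55 ± 0.08 (SD, n = 3 each; 2.49-fold lower). The feedback inhibitors Nkd1 and Axin2 had log2 fold changes of -0.86 and -0.59, and Dkk1, a secreted inhibitor, rose by 0.62. The list was lower in camera (adjusted p = 0.0324; adjusted p = 0.227 with an estimated correlation).

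Genes of cystic kidney disease and cilia rose in 5 of 16 measured members, fell in 1 and did not pass in 10, with the same counts adjusted over the list alone. Of the 16, 15 lay above the median brightness, where 39.6% of all genes passed, so the number past the threshold was not unusual. Pkhd1, the fibrocystin gene of recessive polycystic kidney disease, rose 2.29-fold from 9.33 ± 0.12 to 10.52 ± 0.04 (SD, n = 3 each). Pkd1, also on the miR-200 list, the RNA-binding gene Bicc1 and the ciliary motor gene Kif3a had log2 fold changes of 0.80, 0.59 and 0.49. Ift88, needed to build cilia, had a log2 fold change of 0.00. Camera placed the list higher (adjusted p = 0.0040; adjusted p = 0.227 with an estimated correlation).

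Targets of p53 rose in 10 of 20 measured members, fell in 1 (Fas) and did not pass in 9, with the same counts adjusted over the list alone. Trp53inp1 rose by 1.81 on the log2 scale. Plk2 rose 2.36-fold, Sesn2 2.21-fold and Ccng1 2.10-fold, the last from 10.43 ± 0.07 to 11.50 ± 0.0047 (SD, n = 3 each). Mdm2 and Bbc3, standard p53 targets, had log2 fold changes of -0.10 and 0.05 and did not pass. The list was higher in camera (adjusted p = 3.06e-05; adjusted p = 0.226 with an estimated correlation). Apoptosis effectors moved both ways, with 4 of 14 higher, 4 lower and 6 not past the threshold (the same counts adjusted over the list alone; camera adjusted p = 0.223). Bcl2l11, Bmf and Apaf1 rose by log2 fold changes of 1.32, 0.84 and 0.81, and Bak1 had one of -0.38.

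Genes of S phase fell by small amounts. Of 21 measured members, 11 fell, 1 rose and 9 did not pass (11 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -0.17. The replication genes Gins2, Cdc45 and Tyms had log2 fold changes of -0.46, -0.34 and -0.31, and Ccne2 rose by 0.32. The list was lower in camera (adjusted p = 0.0339; adjusted p = 0.618 with an estimated correlation). It was not called without control replicate 3 (adjusted p = 0.169), without mutant replicate 3 (adjusted p = 0.0811) or with array weights (adjusted p = 0.0502). Of 20 mitosis genes, 5 fell, 1 rose and 14 did not pass (the same counts adjusted over the list alone). Birc5, Ube2c and Aurkb had log2 fold changes of -0.44, -0.34 and -0.33, and Kif23 rose by 0.39. Ube2c lost its call when any of 4 arrays was left out. Camera did not call the mitosis list (adjusted p = 0.175), except without mutant replicate 3 (adjusted p = 0.0497).

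Immediate early genes, which respond to growth factors and to tissue dissociation, were lower in the mutant cells in 9 of 13 measured members, with 4 not past the threshold (the same counts adjusted over the list alone). Junb, Zfp36, Ier2 and Egr1 had log2 fold changes of -0.68, -0.65, -0.62 and -0.47. The list was lower in camera (adjusted p = 0.00486; adjusted p = 0.618 with an estimated correlation) and just missed the threshold in fry (adjusted p = 0.0528). Interferon response genes rose in 4 of 13 measured members, fell in 1 and did not pass in 8 (the same counts adjusted over the list alone). Oasl2 rose 2.00-fold, and Usp18, Bst2 and Ifih1 rose by log2 fold changes of 0.57, 0.54 and 0.45. Only 2 of the 13 interferon genes lay above the median brightness. The list was higher in camera (adjusted p = 0.0339; adjusted p = 0.227 with an estimated correlation). It was not called without control replicate 3 (adjusted p = 0.0546), without mutant replicate 1 (adjusted p = 0.0684) or with dim genes left out (adjusted p = 0.273).

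Imprinted growth genes moved both ways, with 5 of 12 higher, 3 lower and 4 not past the threshold (the same counts adjusted over the list alone; camera adjusted p = 0.200). Igf2r, the receptor that clears Igf2, rose 2.46-fold from 10.31 ± 0.01 to 11.61 ± 0.08 (SD, n = 3 each), Meg3 rose by a log2 fold change of 0.42, and Peg10 and Peg3 fell, at -0.74 and -0.28. Cell junction genes also moved both ways, with 5 of 17 higher, 4 lower and 8 not past the threshold (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.269). Cldn3, Tjp3 and Cdh16 had log2 fold changes of -0.50, -0.49 and -0.32, and Marveld2 rose by 0.56.

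Cell types outside the ureteric lineage were examined through their markers, since the sort could have carried some along. Of 11 cap mesenchyme genes, Six2 and Tmem100 rose (log2 fold changes 3.29 and 0.82), Capn6 (-0.70) and Osr1 (-0.67) fell, and 7, among them Cited1, Eya1 and Gdnf (0.27, -0.05 and -0.15), did not pass. Adjusted over the list alone, 3 were higher and 2 lower, and camera did not call the list (adjusted p = 0.906). Of 7 early nephron genes, Hey1 and Papss2 rose (log2 fold changes 1.62 and 1.06), Wnt4 fell (-0.37) and 4 did not pass (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.312). Of 9 proximal tubule genes, the endocytic receptor Lrp2 rose (1.05), Slc34a1 (-0.69) and Hnf4a (-0.31) fell and 6 did not pass (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.275). The call of Hnf4a (limma, adjusted p = 0.0486) was lost after quantile normalization (adjusted p = 0.0625), after median centring (adjusted p = 0.0718) and when any of 5 arrays was left out. Of 7 genes of the loop of Henle and distal tubule, Irx1 rose (0.48) and 6 did not pass (camera adjusted p = 0.265). Of 6 podocyte genes, Synpo fell (-0.30) and 5 did not pass (camera adjusted p = 0.963).

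Of 13 stromal genes, Acta2 fell (log2 fold change -0.72) and 12 did not pass (camera adjusted p = 0.961). Of 11 endothelial genes, Erg rose (0.47), Plvap fell (-0.42) and 9 did not pass. Camera did not call that list (adjusted p = 0.236), except without control replicate 3 (adjusted p = 0.0454). Of 11 macrophage genes, Ptprc fell (-0.45) and 10 did not pass (camera adjusted p = 0.200). None of 4 erythroid genes passed in limma's test, and 0 did at an unadjusted p under 0.05 (camera adjusted p = 0.744), with log2 fold changes of -0.43 for Hbb-y and -0.06 for Hbb-bh1. Counts for the loop, podocyte, stroma, endothelium, macrophage and erythroid lists were the same adjusted over the list alone. Of these other-lineage calls, those of Osr1, Slc34a1, Irx1, Synpo, Acta2, Plvap and Ptprc were also lost when certain single arrays were left out. All 6 podocyte, 11 macrophage and 4 erythroid genes lay below the median brightness.

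Transcripts over miRNA genes were mostly not past the threshold. Of 296 measured, 22 were higher, 4 lower and 270 did not pass (14 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.269), and 25 of the 296 lay above the median brightness. Mir181b-2 rose 3.36-fold from 5.79 ± 0.19 to 7.54 ± 0.17 (SD, n = 3 each), Mir568 rose 2.52-fold, the host gene Mir100hg 1.88-fold and Mir19b-1 1.76-fold. These probe sets report RNA that covers the miRNA locus, and mature miRNAs were not measured here. The median, the mean and the test differed in sign for the lists of miRNA gene transcripts, cap mesenchyme, stroma, podocyte and embryo sex. Of the embryo sex genes, which vary with the embryos taken, 0 of 4 passed in limma's test and 0 did at an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.963).

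**Figure D2:**
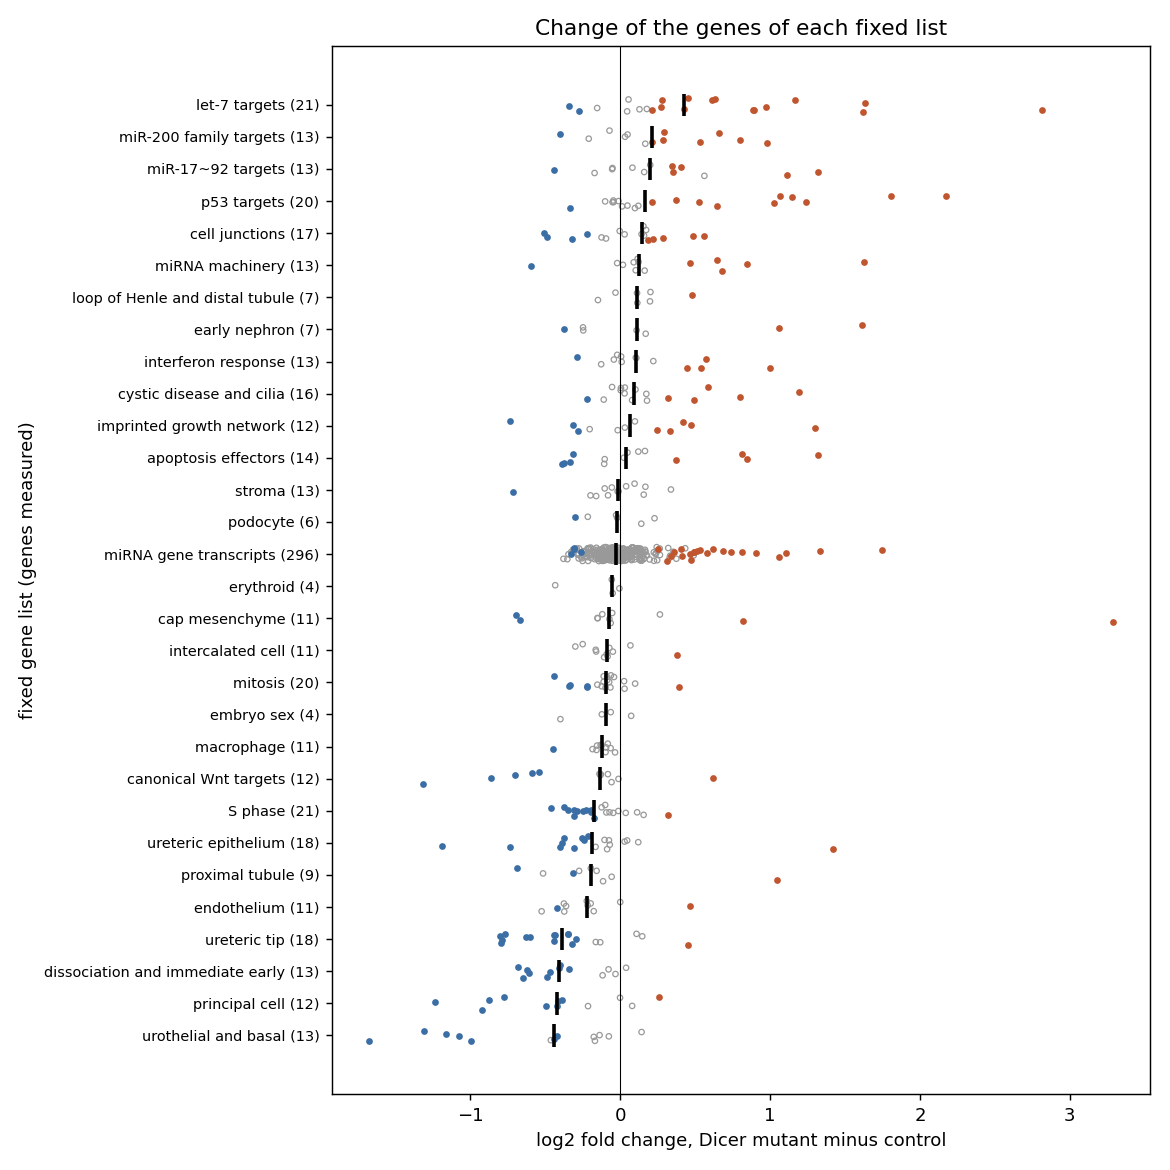
Log2 fold change (Dicer mutant minus control) of every measured gene of the 30 lists, which are ordered by their median. Filled points passed an adjusted p of 0.05 (orange higher, blue lower), open points did not, and black ticks are list medians. The let-7 targets had the highest median, 0.43, and the urothelial and basal genes the lowest, -0.44.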

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

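The tests of explanations in this part, the other splits of the arrays included, were set down only after the results had been seen.

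Signals were also present in probe sets that no comparison used. Of 1174 probe sets that name several genes, 129 (10.99%) passed the threshold, 44 higher and 85 lower in the mutant. Of 1407 probe sets without a gene in the annotation, 250 (17.8%) passed, 95 higher and 155 lower. Among the named probe sets 24.9% passed in the same fit. The changes in the unnamed probe sets ran from -1.57 to 2.72 on the log2 scale.

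The 6 arrays can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 4975 genes past the threshold and the highest of the other splits gave 0, though 183 to 1401 genes in those splits had an unadjusted p under 0.05. In both counts, 1 of the 10 splits, the real one, gave a result as large. The real split gave 14 lists past the threshold and the highest of the other splits gave 8. Single lists were also called in some of the 9 other splits, let-7 targets in 8 of them (smallest adjusted p = 0.00247) and immediate early genes in 6 (0.00196). Among the 14 called lists, at least 1 other split gave a smaller adjusted p than the real one for 6. These were principal cell, urothelial, ureteric epithelium, S phase, interferon and immediate early genes. The same held for uncalled lists, such as endothelium (camera adjusted p = 7.16e-07 against 0.236 in the real split) and mitosis (0.000623 against 0.175). Each of the other splits sets 2 arrays of a genotype and 1 of the other against the rest, so part of the genotype difference remains in it.

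Six2, a gene of nephron progenitors, rose 9.78-fold in cells sorted from another lineage. Cap mesenchyme cells caught in the mutant sort would bring their other transcripts along, but the median log2 fold change of the other 10 cap mesenchyme genes was -0.0947 (95% bootstrap interval -0.41 to 0.10), although Tmem100 rose by 0.82; for the 4 above the median brightness it was -0.37 (-0.70 to 0.27). Hybridization of a related transcript is argued against by Six3, Six4, Six5 and Six6, among which the highest log2 fold change was -0.0427. Expression of Six2 by the mutant bud cells themselves may therefore underlie the rise, as a hypothesis found and tested on the same arrays. Another transcript that matches the probes, or a small cell population with Six2 but not the other markers, stays open.

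Tip genes were lower, with a median log2 fold change of -0.39 (95% bootstrap interval -0.61 to -0.24). More cells of all other lineages in the mutant sort stay open: 79 markers of 9 such lineages had a median of -0.09 (-0.15 to -0.05), but only 17 of them lay above the median brightness, with a median of -0.147 (-0.25 to 0.11). The -0.09 lay near the median of all genes, -0.05, and of genes below the median brightness, -0.07. The intervals resample genes and carry no spread between arrays. More early nephron or distal tubule cells stay open too, since their 14 genes had a median of 0.114 (-0.14 to 0.20). A smaller share of tip cells, which would raise trunk genes, is not decided by the principal cell genes, whose median was -0.419 (-0.83 to -0.11), because slower maturation would lower them and their list was not called with an estimated correlation (an earlier test, on the spread among tip genes from -0.80 to 0.46, decided nothing either). Lower expression per cell in the mutant may add to the pattern, was not tested, and cannot be told apart from these changes in the cells sorted.

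Changes of at least 2-fold were mostly upward, with 144 genes higher and 64 lower, a ratio of 2.25. A difference in scale left between the deposited arrays is argued against as the whole cause, since the ratio was 2.33 after quantile normalization and 2.62 after median centring. After RMA the medians of the deposited arrays still ran from 7.47 to 7.54. Median centring turned the balance of all called genes (2696 higher, 2241 lower), but shifts of that size are small against a 2-fold change. These settings do not test a skew made or hidden by RMA itself, which stays open. By the mean over all arrays the ratio was alike above (2.29) and below (2.16) the median brightness, so by that measure the excess was not confined to dim genes. That mean mixes both groups and does not give the level in control cells. With both group means above the median brightness the ratio was 2.45 (71 higher, 29 lower). This filter leaves out genes that fell below the median, so a 2-fold fall from just above it cannot count. Above the median brightness in control cells the ratio was 1.27 (71 higher, 56 lower), the direction that less room to fall for genes dim in control cells would give. The control filter in turn drops genes that rose from below and keeps genes that fell below. Neither ratio decides the question, and less room to fall stays open. Release of miRNA targets may contribute: 6 of the 144 higher genes and 0 of the 64 lower ones stood among the 47 measured genes of the 3 target lists, which cover too few targets to tell how much of the excess they explain.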

How the results depend on the processing

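The count of genes past the threshold (4975) ran from 3460 without mutant replicate 1 to 6416 with adjusted p under 0.10, and stayed within 1.5 times for all alternatives except stricter thresholds. Requiring 2-fold changes left 208 genes (144 higher, 64 lower), by construction fewer. An unadjusted p under 0.05 with a 1.5-fold change gave 962 (553 higher, 409 lower). As each array was left out, the count of lower genes ran from 1764 without mutant replicate 1 to 2973 without control replicate 3. Dicer1 was called in every alternative run, with log2 fold changes of -0.56 to -0.63 as each array was left out. Of the 26 genes named for the largest changes, each kept its direction and its call in every alternative that tested it; Gabrg1 and Sprr2f were not tested with dim genes left out. Leaving out genes shared between lists changed no list's call or direction.

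Replicate numbers are shared between the groups, but the arrays are not paired by them: deviations of same-numbered arrays correlated at -0.23, -0.09 and -0.19, and none correlated best with its own number. With the replicate block, 3603 genes passed, 3552 of them among the 4975. The block ended the call of S phase (adjusted p = 0.0597) and turned the direction of the uncalled podocyte and embryo sex lists (both adjusted p = 0.986). It changed no other list's call or direction, and of the named genes it ended the call of Plvap (0.0559).

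With an estimated correlation in camera, the adjusted p was 0.0999 for let-7 targets. It was 0.226 for miRNA machinery, miR-200 targets, miR-17 cluster targets, urothelial and basal genes and p53 targets. It was 0.227 for ureteric tip, ureteric epithelium, Wnt targets, cystic disease and cilia, and interferon response. It was 0.618 for principal cell, S phase and immediate early genes. The estimate rests on 6 arrays, and camera with it called the simulated list (adjusted p = 0.0142). The genes of that list varied independently and were all moved alike, so this says little about the real lists. Fry, which does not compare a list with other genes, called apoptosis effectors (adjusted p = 0.0107), imprinted genes (0.00559), cap mesenchyme (0.0139) and early nephron (0.0317). It did not call immediate early genes (0.0528), and it turned podocyte (0.732), stroma (0.701) and embryo sex (0.762).

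Leaving out dim genes ended the calls of miR-17 cluster targets (adjusted p = 0.111) and interferon response (0.273). It turned the uncalled lists of intercalated cells (0.387), stroma (0.357), embryo sex (0.910) and miRNA gene transcripts (0.587). Array weights ended the calls of S phase (0.0502) and Osr1 (0.0656). Hnf4a was not called after quantile normalization (0.0625) or median centring (0.0718). The mean of probe sets turned podocyte (0.981), and quantile normalization (0.896) and median centring (0.958) turned embryo sex. The cause of these shifts was not tested, beyond the fewer genes tested in the first.

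As each array was left out, the adjusted p ran from 0.0145 to 0.115 for ureteric epithelium, 0.0147 to 0.169 for S phase, 0.0203 to 0.0684 for interferon response, 0.0497 to 0.444 for mitosis and 0.0454 to 0.449 for endothelium. Calls were lost without control replicate 3 (ureteric epithelium 0.115, S phase 0.169, interferon 0.0546), mutant replicate 3 (S phase 0.0811) and mutant replicate 1 (interferon 0.0684). They were gained without mutant replicate 3 (mitosis) and control replicate 3 (endothelium). Uncalled lists whose direction turned ran from 0.396 to 0.966 (intercalated cell), 0.749 to 0.936 (cap mesenchyme), 0.649 to 1.00 (podocyte), 0.630 to 0.905 (stroma) and 0.175 to 0.966 (embryo sex). Log2 fold changes ran from -0.80 to 0.19 for Xist and from -0.48 to 0.36 for Uty, and turned without mutant replicate 2 for Xist and without mutant replicate 3 for Uty. Among other named genes, calls were lost for Hnf4a (without 5 of the 6 arrays in turn), Ube2c and Plvap (4 each), Slc34a1 and Synpo (3 each), Osr1, Irx1 and Ptprc (2 each) and Acta2 (1), and gained for Hbb-y, all with their direction kept.

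The planned search for miRNA seed sites in 3' UTRs, with its alternatives, was not run because no transcript sequence was used here. Without detection calls, signal over background could not be given.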

Other observations

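The 7 lists in this part were written after the values had been seen, so their p-values describe these arrays and are no independent evidence. The HoxA cluster, which encodes homeodomain proteins of axial position, was higher in the mutant cells, with 8 of 10 measured genes up, 0 down and a median log2 fold change of 1.03. Hoxa5 rose 4.26-fold from 6.05 ± 0.18 to 8.15 ± 0.10 (SD, n = 3 each), Hoxa3 3.06-fold, Hoxa10 3.03-fold and Hoxa2 2.51-fold (camera adjusted p = 2.68e-09; adjusted p = 0.106 with an estimated correlation). The medians of the other Hox clusters lay between -0.24 and -0.07. In the HoxB cluster 5 of 9 genes were lower and 0 higher (camera adjusted p = 0.0281; adjusted p = 0.243 with an estimated correlation). In the HoxC cluster 1 of 9 was lower, Hoxc9 at a log2 fold change of -0.19 (camera adjusted p = 0.484), a call lost after quantile normalization and median centring. In the HoxD cluster 3 of 9 were lower, and Hoxd10 rose 2.35-fold (camera adjusted p = 0.279). The medians of the HoxA, HoxB and HoxD clusters kept their sign after both scalings.

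Genes of metal handling rose in 5 of 13 measured members and fell in 1 (camera adjusted p = 0.0323; adjusted p = 0.287 with an estimated correlation). The metallothioneins Mt1 and Mt2 rose 4.09-fold and 3.32-fold, the zinc importer Slc39a8 4.04-fold, and the zinc exporter Slc30a1 and the metal-responsive transcription factor Mtf1 by log2 fold changes of 0.56 and 0.52. Slc30a4 fell, at -0.19, a call lost after median centring. The median log2 fold change of the list was -0.07 and its mean 0.45, and the median turned to 0.0008 after quantile normalization. Genes of retinoid and aldehyde metabolism fell in 7 of 14 measured members and rose in 1, Rarb at 0.43 (camera adjusted p = 0.0323; adjusted p = 0.159 with an estimated correlation). Adh1 was 2.94-fold lower, Aldh1a7 2.57-fold, Aldh1a1 2.55-fold and Crabp2 1.71-fold, and the near-identical Aldh1a1 and Aldh1a7 can share probe signal. Genes listed under the cornified envelope fell in 5 of 13 measured members and rose in 0 (camera adjusted p = 0.00172, or 0.106 with an estimated correlation). Krt23, a keratin and not an envelope protein, and Tchh were both 2.53-fold lower, beside Sprr1a, Sprr1b and Sprr2f. The other 8, among them Lor, Ivl and Tgm1, did not pass.

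Genes that differ with embryo sex varied among the mutant arrays. Xist was 10.38, 8.84 and 10.83 on mutant arrays 1, 2 and 3, against 10.41, 10.51 and 10.32 on the control arrays. Uty was 8.26, 8.73 and 7.06 on the mutant arrays, against 8.14, 8.30 and 7.97 on the control arrays. Both Xist and the Y-linked Uty thus lay above the median of all probe sets, 7.51, on each control array. On the control arrays and mutant array 1, Xist lay far above its lowest value, 8.84, and Uty far above its lowest, 7.06. An embryo of either sex would be low in 1 of the 2 genes, so these values argue against 1 embryo per array there. For mutant arrays 2 and 3 this stays open. Whether an array held 1 embryo or a pool is not given in the sources used here, and no test was run. With pools, SDs and p-values would describe the spread between pools and not between embryos.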
